A study of Mus musculus with 2 samples.

How the data were processed

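Cells from the forebrain of mice at postnatal day 0 were dissociated enzymatically and loaded on a droplet instrument, and 1 library per genotype was made with 3-prime chemistry version 3.1, per the labels. Per the labels each library pooled 4 animals from 2 litters, and no mark ties a cell to its animal. The deposited files hold counts of unique molecules (UMIs) per gene and barcode, made with Cell Ranger 7.1.0 on mm10, per the file headers and the submitters' processing notes. They list 28001 features, of which 27998 have Ensembl identifiers and 3 are other sequences, and each barcode has 500 UMIs or more. Other filters by the authors are not given in the sources used here, and no cell annotation was used here. Coordinates came from the GENCODE annotation of the same genome build, in which 27645 features were found by identifier.

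Cells with 1000 or more UMIs and under 10% mitochondrial counts were kept, 10938 in the wild-type and 26178 in the knockout library. Doublets were called with Scrublet in scanpy 1.11.5 per library, with an expected rate of 0.8% per 1000 barcodes. They were 346 of the wild-type cells (3.16%, with 10.4% expected) and 5326 of the knockout cells (20.4%, with 22.1% expected), and were removed. The caller set its own score threshold per library, 0.348 and 0.306. The kept cells held 80259272 and 106183511 UMIs, and the median mitochondrial share of all barcodes was 3.29% in the wild-type and 1.21% in the knockout library. Cells with Xist and no Y-linked UMIs were called female-pattern (7150 wild-type and 9524 knockout cells) and those with UMIs of 4 Y-linked genes and no Xist male-pattern (1594 and 5360).

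Both libraries were clustered together with scanpy and leidenalg 0.10.2, from 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 1, without the genes of the Gmnc and Trp73 programme. Of 44 clusters, 5 stayed unnamed. The others took the name of a marker list, with "-like" added. That list had to score above the others and have at least 3 markers detected in at least 5% of cells. Of the 22 lists, the cycling one was not used for names. Astroglia-like joins apical progenitor and astrocyte clusters. The score minimums, 0.8 for neural and 2.5 for other classes, were set after seeing the data. Names rebuilt this way may differ from those of the study.

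Counts were summed per library and class and divided by their total to give CPM. No test was made, because there is 1 library per genotype and cells are not replicates. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, ratios carry exact conditional intervals, and a count of 0 was taken to allow up to 3 counts. Log2 ratios are knockout over wild-type with 5 CPM added to both values, which understates the ratio of low genes. A list's median was set beside those of 10000 random lists of the same size matched on mean expression, as a description of these libraries, over genes with at least 10 UMIs. Shares of cells with a UMI were also taken after thinning each cell to 2000 UMIs. SciPy 1.17.1 and NumPy 2.4.6 were used.

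The gene lists, the markers and the rule for named genes were fixed before the data were examined. The rule took the 15 highest and 15 lowest log2 ratios over all cells, and the 5 highest and 5 lowest within each class of 200 or more cells in both libraries, among genes at 50 CPM or more in either library. Haemoglobin, mitochondrial, ribosomal protein, Xist, Y-linked and predicted genes were left out, and all genes of the 15 fixed lists could be named; a few genes are not reported here. The calculation was tested on simulated sums of all cells with 200 changed genes among 4214, which held counting error and no other variation between libraries. It gave the right direction for 68 of 68 genes changed 1.5-fold, 63 of 63 changed 2-fold and 69 of 69 changed 4-fold. The 30 genes furthest from the median log2 ratio in either direction were all changed ones. That choice differs from the rule of 15 on each side.

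Alternatives were a looser filter (500 UMIs, 20% mitochondrial), a stricter filter (2000 UMIs, 5% mitochondrial), doublets kept, cells of each sex pattern alone, resolutions of 0.5 and 2, clustering with the programme genes or without the Cajal-Retzius markers, median-of-ratios scaling, a mean over cells, a prior of 1 CPM, no thinning, and cells picked by 3 or more Cajal-Retzius markers. Added after seeing the data were clustering without the 200 leading genes of the Cajal-Retzius-like and the ependymal-like cluster, cells picked by 3 or more ependymal markers, and both marker picks with doublets kept. The ependymal-like share and the single named genes had no alternatives of their own in the plan and were put through the same ones afterwards.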

Results

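Single-cell RNA sequencing counted messenger RNA molecules in forebrain cells of mice at postnatal day 0. There were 2 libraries, 1 from wild-type animals and 1 from littermates without Gmnc, each a pool of cells from 4 animals of 2 litters. The dissected tissue held the lateral and dorsal cortex and the hippocampus. Gmnc (GemC1) is a coiled-coil protein that starts the multiciliated cell programme, and Trp73 and Mcidas act in the same programme. The title of the series asks what Cajal-Retzius neurons that carry p73 and the secreted protein Reelin contribute to the shape of the cortex. The wild-type library held 88905819 unique molecular identifiers (UMIs) in 13033 barcodes and the knockout library 155482657 UMIs in 27663 barcodes. After filtering, 10592 wild-type and 20852 knockout cells remained, with a median of 6022 and 4477 UMIs. With 1 library per genotype no difference below has a replicate check, and each compares these 2 libraries, not the genotypes. Intervals in parentheses are 95% intervals that cover counting error only.

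Gmnc itself gave 66 UMIs in the wild-type library and 86 in the knockout library, or 0.822 (0.636 to 1.05) and 0.81 (0.648 to 1.0) CPM, the usual depth-scaled count. Gmnc (ENSMUSG00000068428) lies on chromosome 16 from 26913553 to 26991652 of mm10. The sources used here do not give the deleted part, and a tag at the 3-prime end may lie outside it, so these counts check nothing about the genotype labels. In cells with a female expression pattern the knockout-to-wild-type ratio was 0.466 (0.277 to 0.762), and in cells with a male pattern it was 1.93 (0.88 to 4.80).

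Cajal-Retzius-like cells, the early-born Reelin-secreting neurons of the cortical surface, were scarce in the knockout library. They made up 38 of 10592 wild-type cells, or 0.359% (0.254% to 0.492%), and 2 of 20852 knockout cells, or 0.00959% (0.00116% to 0.0346%). The ratio of the shares was 0.0267 (0.00313 to 0.103). Cells with UMIs of at least 3 of the 10 Cajal-Retzius markers, picked without regard to clusters and after thinning every cell to 2000 UMIs, numbered 43 of 8751 in the wild-type and 3 of 17939 in the knockout library. This share had a ratio of 0.034 (0.00675 to 0.106). In 2 settings, a stricter cell filter and doublets kept, the named cluster also took in interneuron-like cells and the ratio was 0.502 and 0.452, although a single knockout cell in it held a Trp73 UMI in each. In male-pattern cells alone, with 2 wild-type cells and 1 knockout cell in the class, the ratio was 0.149 (0.00252 to 2.86). Of the 38 wild-type cells, 33 held Trp73. After the values were seen, 1 of them was noted to hold 1024 UMIs of Gnrh1, the gonadotropin-releasing hormone, and 0 of Reln, and another held 1 UMI of Reln, 0 of Trp73, Lhx1, Lhx5 and Ndnf, and 3 of Sst. Of the 2 knockout cells, 1 held 90 Reln and 3 Trp73 UMIs and the other held 2 Reln and 0 Trp73 UMIs.

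**Figure D1:**
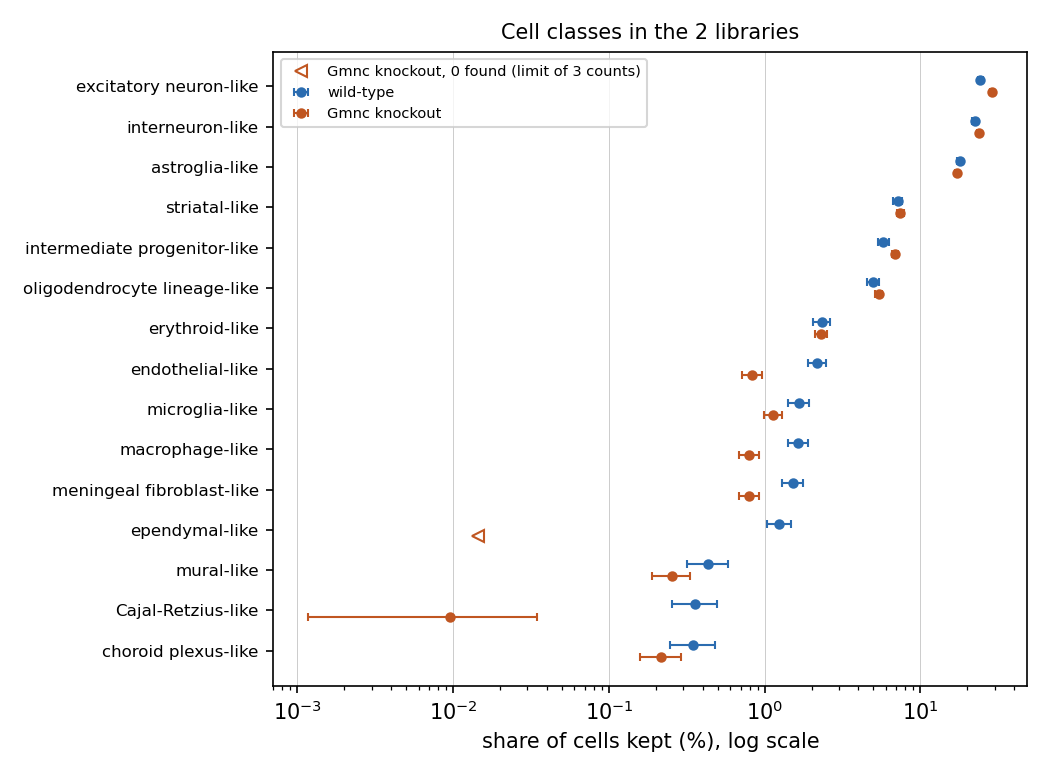
Share of cells in each named class (%, log scale) in the wild-type and the Gmnc knockout library, with exact 95% intervals. The open triangle marks the limit that 0 cells allow. Ependymal-like and Cajal-Retzius-like cells show the widest gaps between the 2 libraries.

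Trp73, which encodes the transcription factor p73, was at 5.47 CPM (4.97 to 6.01) in the wild-type and 0.132 CPM (0.0721 to 0.221) in the knockout library. A Trp73 UMI was found in 192 wild-type cells (1.81%) and 12 knockout cells (0.0575%). After thinning to 2000 UMIs, which left out 1841 wild-type and 2913 knockout cells, there were 51 cells (0.583%) and 2 cells (0.0111%), a ratio of 0.0191 (0.00226 to 0.0727), and 0.0731 (0.00148 to 0.738) in male-pattern cells. In the wild-type library Trp73 was seen in 86.8% of Cajal-Retzius-like and 67.2% of ependymal-like cells before thinning. Erythroid-like cells, which should lack the gene, gave 1 of 247 in the wild-type and 0 of 480 in the knockout library, which allows a share of up to 0.625%, at median depths of 5984 and 3985.5 UMIs. These cells were not the same background in both libraries, since in the knockout library they held less of the erythroid gene Hemgn (69.1 and 4.57 CPM) and more of the axon guidance receptor gene Dcc (24.3 and 199 CPM), which holds for each background value below. Excitatory neuron-like cells gave 0.583% and 0.05%.

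Of the 10 Cajal-Retzius identity genes, 9 were lower in the knockout library. The list had a median log2 ratio of -0.33, below all but 0.01% of 10000 random lists matched on expression. It was -0.88 with a prior of 1 CPM and -0.18 in male-pattern cells. The LIM-homeobox gene Lhx1 was at 1.42 and 0.132 CPM and Lhx5 at 0.959 and 0.0753 CPM in the wild-type and the knockout library. Ndnf was at 14.3 and 4.65 CPM, and Ebf3 at 2.31 and 0.772 CPM. Calb2 (37 and 38.7 CPM) and Cacna2d2 (8.80 and 8.41 CPM), which other neurons also express, had overlapping intervals.

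**Figure D2:**
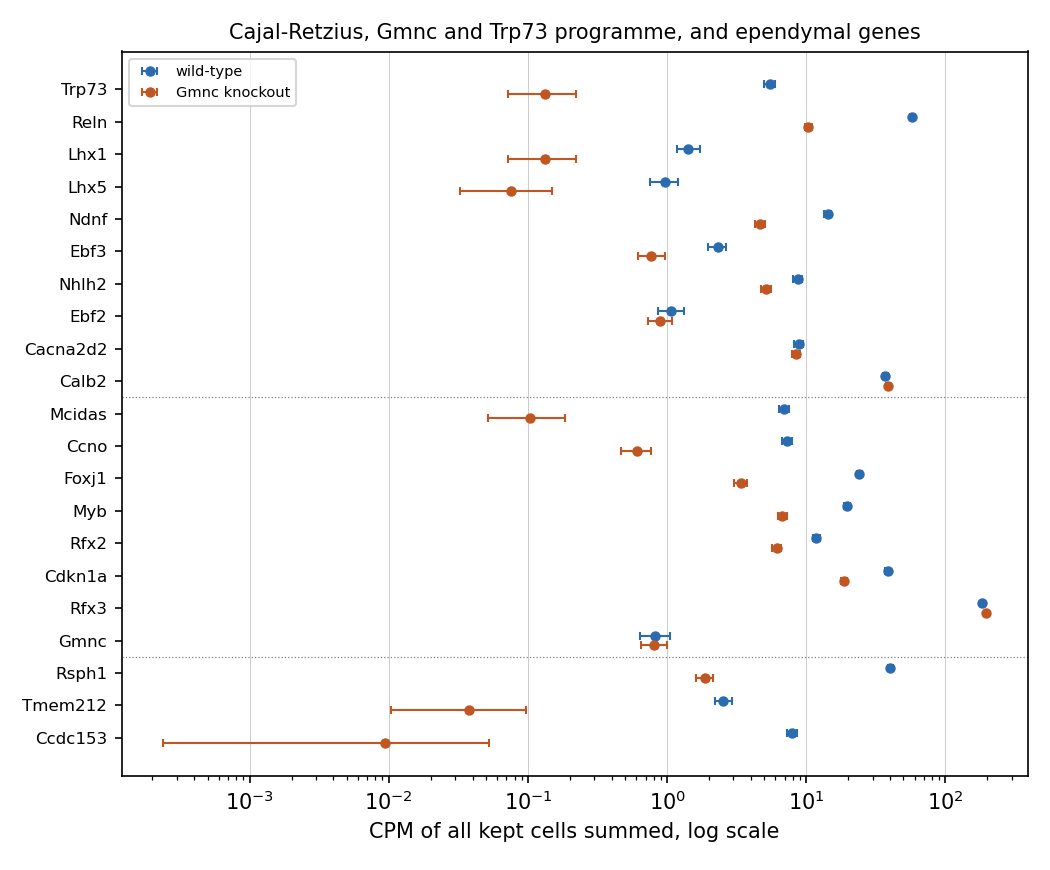
CPM over all kept cells (log scale) of the 10 Cajal-Retzius genes, Trp73 among them (top), the other genes of the Gmnc and Trp73 programme (middle) and 3 ependymal genes (bottom), with exact Poisson 95% intervals. Trp73, Mcidas and Ccdc153 lie far apart in the 2 libraries, and Gmnc, Calb2 and Rfx3 lie close together.

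Reln, which encodes Reelin, was 5.53-fold lower in the knockout library (5.17 to 5.91), at 57.1 CPM (55.5 to 58.8) in the wild-type and 10.3 CPM (9.73 to 11) in the knockout library. The log2 ratio was -2.02, and -1.25 in male-pattern cells. Cajal-Retzius-like cells held 67.9% (66.5% to 69.2%) of the Reln UMIs of the wild-type library and 8.39% (6.81% to 10.2%) of those of the knockout library, where 90 of the 92 UMIs came from 1 cell. Excitatory neuron-like cells held 11.5% and 36.6%, and interneuron-like cells 6.57% and 24.9%. Outside Cajal-Retzius-like cells Reln was at 18.4 CPM (17.5 to 19.4) and 9.47 CPM (8.89 to 10.1). After thinning, a Reln UMI was seen in 2.76% of wild-type and 0.513% of knockout erythroid-like cells, with median depths of 7072 and 4765 UMIs. In excitatory neuron-like cells this share was 2.56% and 1.78%, so the wild-type value was no higher than this background. In interneuron-like cells it was 3.75% and 0.983%, within the counting interval of the background in each library (1.02% to 5.92% and 0.0622% to 1.84%), but this class is mixed. Its cluster 37, with 48 wild-type and 74 knockout cells, held 113 of the 301 wild-type and 188 of the 273 knockout Reln UMIs of the class. Reln was at 468 and 626 CPM there, but the cluster did not hold the same cells in both libraries, since Sst was at 87 and 1750 CPM, Npy at 145 and 1420 CPM and Prox1 at 207 and 69.9 CPM.

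**Figure D3:**
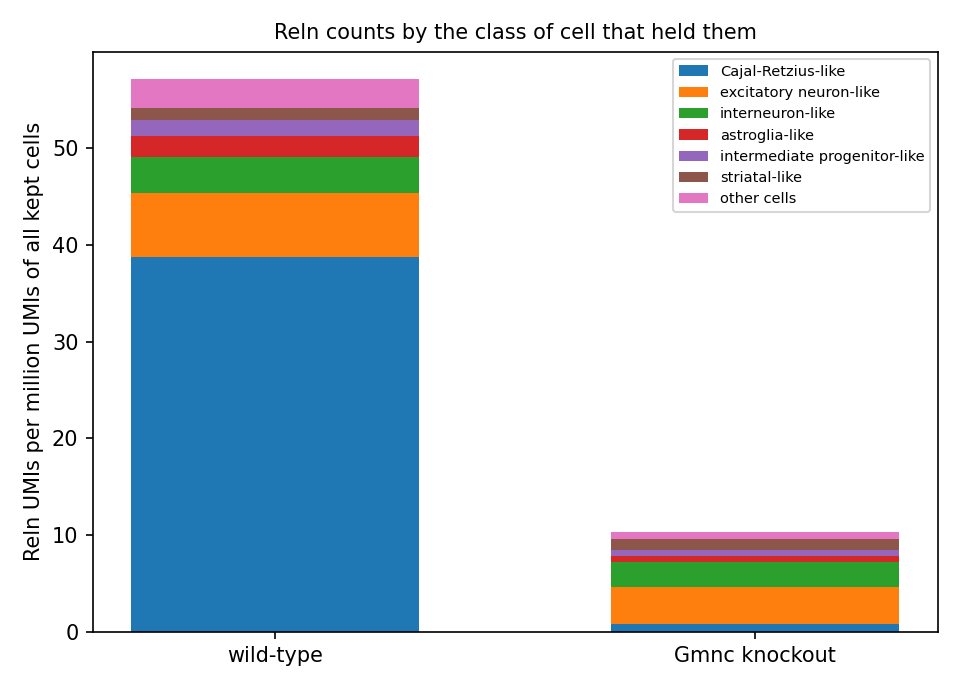
Reln counts in CPM over all kept cells of each library, stacked by the class of cell that held them. Cajal-Retzius-like cells hold 67.9% of the wild-type and 8.39% of the knockout Reln UMIs.

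Ependymal-like cells, the multiciliated cells that line the ventricles, numbered 131 of 10592 in the wild-type library, or 1.24% (1.03% to 1.47%). The knockout library held 0 of 20852, which allows a share of up to 0.0144% with 0 set to 3 cells. By that limit the share was at least 86-fold lower, and at least 68.9-fold with the counting error of both libraries. With 1 library per group a cluster of 1 library alone may belong to that library and not to a type. Without regard to clusters, 23 wild-type and 0 knockout cells held UMIs of at least 3 of the 4 ependymal markers after thinning. When the leading genes of both clusters were left out of the clustering, choroid plexus-like and ependymal-like cells merged in part. The named cluster then held 131 wild-type and 47 knockout cells, a ratio of 0.182 (0.128 to 0.256). This was fewer wild-type cells than the 131 ependymal-like and 37 choroid plexus-like cells of the main clustering together. The ciliary gene Rsph1 was at 40.3 CPM in the wild-type and 1.87 CPM in the knockout library, and Ccdc153 gave 633 and 1 UMIs, a ratio of 0.00119 (3.02e-05 to 0.00668).

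Over all cells the 9 genes of the Gmnc and Trp73 programme had a median log2 ratio of -1.03, and 8 of them were lower in the knockout library. All of the 10000 matched random lists had a higher median. As a mean over cells the median was -0.54, and in male-pattern cells -0.61. Mcidas, the partner of Gmnc in starting multiciliation, was at 6.94 and 0.104 CPM in the wild-type and the knockout library, and the cyclin gene Ccno at 7.26 and 0.603 CPM. Foxj1, the regulator of motile cilia genes, was at 24.1 and 3.39 CPM and Myb at 19.6 and 6.73 CPM. Rfx3, which neurons also express, was at 182 and 195 CPM. Ependymal-like cells, absent by cluster from the knockout library, held 534 Mcidas, 518 Ccno, 1526 Foxj1 and 1042 Myb wild-type UMIs. The list median over all cells in part restates this. Within neural classes it was -0.10 in excitatory neuron-like (percentile 2.38) and -0.14 in interneuron-like cells (2.21). It was -0.045 in striatal-like (27.25), -0.017 in astroglia-like (10.6), 0.012 in oligodendrocyte lineage-like (37.9) and 0.28 in intermediate progenitor-like cells (89.3). Foxj1 was seen after thinning in 1.61% of wild-type and 0.463% of knockout cells, in 0 of 217 and 0 of 390 erythroid-like cells, and in 1.09% and 0.749% of astroglia-like cells. In choroid plexus-like cells the 5 programme genes that could be measured had a median of 0.62 (0.22 to 0.91, percentile 95.6). Foxj1 was higher there in the knockout library, at 67.7 and 110 CPM. The rise was not special to the programme, since in these cells upper-layer genes had a median of 0.65 and deep-layer genes 0.48, but hippocampal genes 0.03.

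Among the 15 named classes, 10 had a lower share in the knockout library and 5 a higher one. The interval of the ratio included 1 for astroglia-like (0.961, 0.909 to 1.016) and erythroid-like cells (0.987, 0.845 to 1.156). It also did for oligodendrocyte lineage-like (1.088, 0.981 to 1.21) and striatal-like cells (1.04, 0.953 to 1.136). Endothelial-like cells made up 2.18% (1.91% to 2.48%) of wild-type and 0.83% (0.711% to 0.962%) of knockout cells. Macrophage-like cells made up 1.64% and 0.796%, meningeal fibroblast-like cells 1.51% and 0.796%, microglia-like cells 1.65% and 1.13% (a ratio of 0.685, but 0.954, 0.814 to 1.12, with doublets kept), mural-like cells 0.434% and 0.254%, and choroid plexus-like cells 0.349% and 0.216%. Excitatory neuron-like cells made up 24.3% and 28.8%, intermediate progenitor-like cells 5.79% and 6.88%, and interneuron-like cells 22.3% and 23.7%. Shares sum to the whole, so a lower share of some classes raises the others, and cells in unnamed clusters made up 5.94% and 4.30%. Doublets were called in 3.16% of wild-type and 20.4% of knockout cells, and the summed share of the 5 vascular, immune and meningeal classes had a ratio of 0.513 with them removed and 0.735 with them kept.

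In excitatory neuron-like cells the median log2 ratio of 7 upper-layer genes was 0.10 (percentile 52.7 of the random lists), but -0.0019 (-0.036 to 0.043) under median-of-ratios scaling, 0.012 with doublets kept, 0.024 as a mean over cells and 0.19 with a looser cell filter. That of 9 deep-layer genes was -0.07 (percentile 8.79), but -0.17 (-0.24 to -0.11) under median-of-ratios scaling, 0.17 (0.050 to 0.32) in male-pattern cells and 0.023 (-0.044 to 0.050) as a mean over cells. Cux2 was at 208 and 241 CPM, Tle4 at 157 and 190 CPM and Bcl11b at 186 and 163 CPM in the wild-type and the knockout library. Of 6 hippocampal genes, 4 could be measured and each was higher in the knockout library, with a median of 0.37 (percentile 99.4). This was not special to the class, since the median was 0.32 in interneuron-like cells (percentile 97.3), 0.36 in astroglia-like cells (95.6) and 0.67 in microglia-like cells (98.2), but -0.60 in macrophage-like cells (1.54). The transcription factor gene Zbtb20 among them was at 1850 and 2540 CPM. Clusters 0 and 1 held most of this class in both libraries, with 43.8% and 25.6% of its wild-type and 40.3% and 31.7% of its knockout cells.

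The 11 genes of Reelin signalling had a median log2 ratio of 0.08 (percentile 40.6) in excitatory neuron-like cells, but -0.015 (-0.040 to 0.051) under median-of-ratios scaling, 0.035 as a mean over cells, 0.16 in male-pattern cells and 0.20 with a stricter cell filter. The receptor gene Lrp8 (ApoER2) was at 230 CPM (223 to 238) in the wild-type and 383 CPM (376 to 390) in the knockout library. The other receptor gene, Vldlr, was at 36.7 CPM in both, and the adaptor gene Dab1 at 716 and 749 CPM. Lrp8 was also higher in cluster 37 of the interneuron-like cells, at 112 and 186 CPM, a ratio of 1.67 (1.04 to 2.74) from 27 and 56 UMIs. That cluster did not hold the same cells in both libraries, so whether the difference was limited to excitatory neuron-like cells stays open. In choroid plexus-like cells Lrp8 was at 148 and 199 CPM, with an interval of the ratio that included 1 (0.975 to 1.85). Over all cells the list had a median of 0.30 (percentile 85.5).

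Across 15 lists and the 6 neural classes, 83 combinations could be measured, and 19 had a median outside the central 95% of random lists, 17 below and 2 above. The number was 10 with a stricter cell filter and 4 in male-pattern cells. Cajal-Retzius identity genes were below it in 6 of 6 classes, with 4 to 10 genes measured per class. UMIs of these genes, Reln among them, may include free RNA. Erythroid-like cells gave an unequal background for it, and its part in these medians was not measured. Cell cycle genes were below that central range in 4 of 6. The random lists were matched on expression and not on gene length, although longer genes had higher log2 ratios across 5600 genes (Spearman 0.452). List percentiles and genes named by size may reflect length in part, which was not tested for the lists. Over all cells 6 of 9 cell cycle genes were lower in the knockout library, with a median of -0.28 (percentile 0.84), but Mki67 was higher, at 128 CPM in the wild-type and 203 CPM in the knockout library, and Cdk1 lower, at 90.6 and 35.1 CPM. Among astroglia-like and intermediate progenitor-like cells, 26.4% (24.6% to 28.2%) of wild-type and 29.1% (27.8% to 30.4%) of knockout cells held an Mki67 or Top2a UMI after thinning, a ratio of 1.10 (1.0 to 1.21). Before thinning the shares were 36.4% and 37.3%.

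Over all cells each of the 8 microglial activation genes was lower in the knockout library, with a median log2 ratio of -0.74 (percentile 0.01), beside a share of microglia-like cells that was lower with doublets removed and not detectably so with them kept. Within microglia-like cells 7 of 8 were lower, with a median of -0.51 (percentile 0.07). Spp1 (osteopontin) was at 5920 and 2590 CPM and the galectin gene Lgals3 at 343 and 169 CPM in these cells, while the lipase gene Lpl was at 268 and 267 CPM. Each of the 10 dissociation and immediate early genes was lower over all cells (median -0.37, percentile 0.02), as was each of the 5 interferon response genes (median -0.48, percentile 0.51). Hypoxia and glycolysis genes had a median of -0.41 (percentile 0.39) and the chemokine axis of meninges and Cajal-Retzius cells -0.44 (percentile 2.55). The remaining lists over all cells had medians of 0.32 for upper-layer (percentile 86.6), 0.21 for deep-layer (64.4), -0.12 for subplate and layer 6b (19.6), 0.30 for hippocampal (99.3), 0.05 for subiculum-associated (39.2) and 0.03 for p53 and apoptosis genes (41.7).

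Among 4328 genes at 50 CPM or more in either library, the median log2 ratio was 0.18. The 15 genes with the lowest ratios were Ptgds, Hist1h2ap, Reln, Spp1, Ttr, Chchd10, Igfbp7, Cdk8, Apod, Lgmn, Pfn1, Junb, Klf2, Vtn and Hopx. Ptgds, the prostaglandin D2 synthase of meninges and choroid plexus, was at 437 CPM in the wild-type and 71.3 CPM in the knockout library, and Ttr, the transthyretin of the choroid plexus, at 578 and 186 CPM. Ttr was also at 66.0 and 9.39 CPM in astroglia-like cells, and over all male-pattern cells its log2 ratio was 2.79. Igfbp7 and Vtn are genes of vascular and mural cells, whose shares were lower as well. The 15 highest were Filip1l, Phykpl, Paxbp1, Cntn2, Dlx1, Tro, Chd5, Scrt1, Cplx2, Thra, Sorbs2os, Kif5a, Chd3, Kif1a and Sez6l2. The kinesin gene Kif5a was at 57.8 and 124 CPM and the kinesin gene Kif1a at 108 and 225 CPM. Dlx1, a transcription factor gene of interneurons, was at 91.6 and 211 CPM, but Dlx2, another interneuron marker, went the other way. Over the 5 neural classes other than oligodendrocyte lineage-like, the median log2 ratio was 0.687 for Dlx1 and -0.813 for Dlx2. Dlx1 alone thus does not stand for interneuron genes.

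Of the genes among the 5 lowest or 5 highest within the 6 neural classes, 5 were so in at least 4 classes, a minimum set after the values were seen. Cdk8 was among the 5 lowest in 6 of 6 and Hist1h2ap in 4, and Filip1l was among the 5 highest in 6 of 6, Paxbp1 in 5 and Phykpl in 5. In excitatory neuron-like cells Cdk8, a kinase of the Mediator complex, was at 527 and 172 CPM and Filip1l at 20.2 and 96.7 CPM. Histone genes such as Hist1h2ap have near-identical copies, so their counts are uncertain. The calcium-binding gene S100a10 (113 and 32.8 CPM) and the neurofilament gene Nefl (58.4 and 21.0 CPM) were among the lowest in this class, although Nefl had a log2 ratio of 0.44 (-0.15 to 1.07) in male-pattern cells. Cluster 17, in which Nefl and Nrgn were leading genes, held 12.5% of the class in the wild-type and 7.02% in the knockout library. In intermediate progenitor-like and astroglia-like cells the Wnt modulator gene Sfrp1 was among the highest, at 101 and 233 CPM in the former and 184 and 413 CPM in the latter. Dlx1 was among the highest in oligodendrocyte lineage-like cells, at 70.1 and 217 CPM. In erythroid-like cells the 5 highest were Dcc (24.3 and 199 CPM), Nrg1 (47.5 and 348 CPM), Kcnd2, Chd3 and Unc5d, and the lowest included the haem synthesis gene Cpox (82.9 and 3.20 CPM).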

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

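The reference of the files held sequences of a fluorescent reporter, named Stop-Ai9 and Tomato, which the comparisons did not use and for which the labels name no reporter allele. Stop-Ai9 counts stood at 570 CPM in the wild-type library, where a count of 0 allows 0.0374 CPM. In the knockout library Stop-Ai9 stood at 197 CPM, where a count of 0 allows 0.0283 CPM. Tomato stood at 31.8 CPM in the wild-type and 14.1 CPM in the knockout library. Within the wild-type library Stop-Ai9 stood at 510 CPM in female-pattern and 812 CPM in male-pattern cells. Within the knockout library it stood at 26.5 CPM in female-pattern and 413 CPM in male-pattern cells.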

How the results depend on the processing

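The shares of Cajal-Retzius-like, ependymal-like and Trp73 cells were lower in the knockout library under each alternative run. So were Reln and the programme and Cajal-Retzius lists over all cells. Clustering without the leading genes, the ependymal marker pick and the marker picks with doublets kept were added after seeing the data, as were all alternatives for the ependymal-like share and for single genes. The size of these differences moved. With the looser filter the log2 ratio of Reln was -2.24, and the Cajal-Retzius list median was -0.38 and the upper-layer median 0.19. With the stricter filter the Cajal-Retzius-like ratio was 0.502, Reln -1.69, the Cajal-Retzius median -0.27, Reelin signalling 0.20, and 10 list and class combinations lay outside the random lists. With doublets kept the Cajal-Retzius-like ratio was 0.452, the cycling ratio 1.23, the programme median -0.93 and the upper-layer median 0.012. In those settings 53 and 71 of the 55 and 93 knockout cells so named had been interneuron-like.

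In female-pattern cells the ependymal-like ratio, with 0 knockout cells set to 3, was 0.0242, the Gmnc ratio 0.466 and the programme median -1.10. Male-pattern cells were few, with 1594 in the wild-type library. In them the Cajal-Retzius-like ratio was 0.149 (2 wild-type cells and 1 knockout cell), the ependymal-like ratio 0.0811 by the same floor, Trp73 0.0731, Gmnc 1.93, Reln -1.25, the Cajal-Retzius median -0.18, the programme median -0.61 and Reelin signalling 0.16, and 4 combinations lay outside. Also in male-pattern cells the deep-layer median reversed to 0.17, Ttr over all cells to 2.79, Hist1h2ap in erythroid-like cells to 0.56, Nefl in excitatory neuron-like cells to 0.44 and Cks2 in oligodendrocyte lineage-like cells to 0.20, and the cause was not tested. The counting intervals of the last 3 included 0.

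Under median-of-ratios scaling Reln was -2.13 and the deep-layer median -0.17, while the upper-layer median reversed to -0.0019 and Reelin signalling to -0.015, with intervals that included 0. This scaling takes out the median shift of the class, which was 0.12. As a mean over cells the programme median was -0.54, the upper-layer median 0.024 and Reelin signalling 0.035, and the deep-layer median reversed to 0.023, with 0 in its interval, the cause not tested. With a prior of 1 CPM, which shrinks low genes less, Reln was -2.36, the Cajal-Retzius median -0.88 and the programme median -1.41. The ependymal-like ratio was 0.182 without the leading genes. By markers no knockout cell was found, and with 0 set to 3 the ratio was 0.0636 (upper counting bound 0.0849), and 0.0517 (0.0689) with doublets kept, limited by 23 wild-type cells. Of the other values for comparisons 57 planned and 10 added ones lay within the counting interval or 1.5 times the count. For single genes 506 lay within it, 280 moved in size and 4 reversed. No paired analysis was possible because there was 1 library per genotype. With 1 library each, depth limits the rare classes, and single animals cannot be told apart.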

Other observations

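The tests of depth, surface tissue and ventricular tissue for the scarce classes, that of the microglia-like share, the marker picks with doublets kept and the values in the next 3 paragraphs were chosen after their results were seen.

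An unnamed cluster led by Crym and Enkur, among others, with 273 wild-type and 477 knockout cells, also expressed genes of motile cilia. Its cells had Foxj1 at 57.1 CPM (48.3 to 67.0) in the wild-type and 43.8 CPM (36.6 to 52.0) in the knockout library and Enkur at 191 and 168 CPM, while Rsph1 was at 60.9 CPM (51.8 to 71.1) and 26.5 CPM (20.9 to 33.0). It made up 2.58% of wild-type and 2.29% of knockout cells. Another unnamed cluster, led by the mast cell protease genes Cma1 and Cpa3, held 138 wild-type cells (1.30%) and 61 knockout cells (0.293%). It scored highest on the microglia list but below the minimum set after seeing the data, as did a cluster of 4 wild-type cells (0.0378%) and 25 knockout cells (0.12%), while a cluster scoring highest on the erythroid list (1.89% and 1.52%) also stayed below it.

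In cluster 17 of the excitatory neuron-like cells Nefl was at 228 and 139 CPM and Nrgn, a calmodulin-binding gene of forebrain neurons, at 847 and 633 CPM in the wild-type and the knockout library. Over the whole class Nrgn was at 216 and 89.1 CPM and the transcription factor gene Mef2c at 979 and 589 CPM.

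Among wild-type female-pattern astroglia-like cells of 8000 UMIs or more, 31.7% held 0 or 1 Stop-Ai9 UMI, where a single Poisson rate gives 0.934%. In wild-type male-pattern cells this share was 1.03%, where a single rate gives 0.0782%. In knockout male-pattern cells it was 10.4%, where a single rate gives 4.87%, and in knockout female-pattern cells 97.2%, where a single rate gives 97.7%.

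Cajal-Retzius-like and ependymal-like cells were scarcer in the knockout library. Lower depth was not enough to account for the scarcity of Trp73 cells, whose share kept a ratio of 0.0191 (0.00226 to 0.0727) after thinning. Trp73 is itself a gene of the programme, so this value alone does not decide on depth for the 2 classes. The thinned picks by 3 or more markers had a ratio of 0.034 (0.00675 to 0.106) for Cajal-Retzius markers. For ependymal markers the upper counting bound was 0.0849. With doublets kept, cells with 3 or more Cajal-Retzius markers had a ratio of 0.0264 (0.00525 to 0.0823). There, 3 or more ependymal markers were held by 0 of 22926 knockout and 23 of 9081 wild-type cells, a ratio with an upper counting bound of 0.0689. Sorting into other clusters or removal as doublets was thus not enough for cells that kept these markers. Cells that lost the markers would be missed, since Trp73 and Foxj1 of the programme are among the markers of the 2 picks. Less surface tissue would bring the Cajal-Retzius-like ratio to that of meningeal fibroblast-like cells, but it was 0.0507 (0.00587 to 0.203) of theirs. The ependymal-like ratio was 0.0188 (0.00363 to 0.0651) of the choroid plexus-like one, with 0 knockout cells set to 3. These values go with a loss, without Gmnc, of these 2 classes or of the marker transcripts that name them. The 2 readings cannot be told apart here, and they were found and tested on the same libraries. Not all cells with cilia genes were missing, since Foxj1 was at 67.7 and 110 CPM in choroid plexus-like cells and the cluster with Enkur made up 2.58% and 2.29%. Differences between the pooled animals or the 2 dissections stay open.

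The 5 genes named in at least 4 of the 6 neural classes, Cdk8, Filip1l, Hist1h2ap, Paxbp1 and Phykpl, shifted alike in all 6, a definition chosen after seeing the data. Gene length was related to the shift across 5600 genes, which are not independent replicates (Spearman 0.452). Removing the trend left 1.01 of the median shift of the 5. The 5 were picked for extreme shifts, with a median size of 1.71, where the standard deviation over genes of astroglia-like cells was 0.385. A trend over all genes could hardly take out such a shift, so no conclusion about length is drawn. Female-pattern cells alone kept 0.992 of the shift, which argues against sex make-up, although the 5 were picked with these cells included. Variants linked to the Gmnc locus stay open, because 1 of the 5 (20%), Filip1l, lay on chromosome 16 within 40 Mb of Gmnc, against 2.78% of the genes tested, and 5 genes are too few to decide. A difference in genotype cannot be told apart from any other difference between the 2 libraries for the remaining genes.

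Vascular, immune and meningeal classes made up 7.42% of wild-type and 3.81% of knockout cells. Fuller removal of the meninges could account for the meningeal classes and would leave microglia-like cells, which lie in the tissue itself, at a ratio of 1, but theirs was 0.685 (0.561 to 0.838). With doublets kept, a value added after the result was seen, it was 0.954 (0.814 to 1.12), so this explanation, which the first value alone would exclude, was left open. Removal of more such cells as doublets from the knockout library may account for part, since the ratio of the summed share went from 0.513 to 0.735 with doublets kept, between the bounds set beforehand of 0.7 and 0.9. Neither explanation can be told apart from a difference in genotype.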
